A study of Mus musculus with 9 samples.

How the data were processed

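Poly(A) RNA was sequenced from bulk liver of male C57BL/6J mice that had eaten a high-fat diet for 20 weeks. Per the labels' protocols, mice arrived at 7 weeks of age, acclimated for 1 week, started the diet at 8 weeks of age and were 28 weeks old at the end. Formoterol at 1 mg/kg or its DMSO vehicle was injected into the peritoneum every day in the last 4 weeks. RNA was isolated on columns with DNase treatment, and complementary DNA was made from fragmented poly(A) RNA with random primers, per the labels' protocols.

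The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library, and the values are whole numbers that have not been normalized. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the mouse genome build mm39, and DESeq2 was also used, with no version given and no trace of it in the counts. The counting program, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Reads of near-identical copies can be split or dropped by counting, so values of the major urinary protein genes, the Cyp2a, Cyp2b and Cyp2c families, the Ugt1a locus, Serpina1c, Serpina3k, Orm1, Saa4, Gstm1, Eno1 and the zinc finger gene Zfp969 are uncertain. The table gives symbols, coordinates on mm39, a biotype and a length in bp for each gene, and all 56748 genes had a name or identifier.

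The columns of the table carry animal codes (M46 to M60) and a group suffix, and no replicate number of the labels. Codes M46, M47, M48, M49 and M50 share 1 suffix and were taken as the formoterol group, and codes M56, M58, M59 and M60 share the other and were taken as the vehicle group. The basis is the last letter of the suffix together with the group sizes of 5 and 4 that the design text gives. The direction of each comparison rests on that reading. The design text counts mice, and each library was taken as 1 mouse. If libraries shared an animal, the p-values would measure only the spread between these samples, which may be technical.

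Totals ranged from 12336665 to 20339665 counts per library. Of the 56748 genes, 24041 had at least 1 count and 13042 were kept for testing by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. That minimum corresponded to 0.6 CPM (counts scaled to a common library total) in at least 4 libraries. The genes kept held over 99.8% of the counts in each library, so only genes of low abundance were lost. Formoterol and vehicle were compared with edgeR 4.0.16 in R 4.3.3, using TMM factors, the robust quasi-likelihood test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Log2 fold changes are formoterol minus vehicle, given with their standard error (SE). CPM values are normalized with TMM factors and given as mean ± SD over 4 vehicle and 5 formoterol libraries.

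The 40 gene lists, the edgeR test, camera and fry, most alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01 and adjusted over the 40 lists by the Benjamini-Hochberg method. Camera asks whether the genes of a list rank higher or lower than the other genes. Camera with a correlation estimated from the data, and fry, were run beside it (limma 3.58.1). A list score per library is the mean over its genes of log2 CPM (prior count 2) minus the mean of the 9 libraries, and scores were compared by two-sided exact permutation tests, which were chosen after the data were seen. With 4 against 5 libraries there are 126 splits, so that test cannot give a p below 0.00794. No score could pass the adjustment over 40 lists unless several reached that limit.

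Named genes are those with the smallest p in each direction (up to 5, since none passed), up to 4 genes per list described, and a fixed set of adrenergic and metabolic genes plus the most abundant gene. The rule of the 10 largest changes in each direction was applied again to a comparison without formoterol library M49, which was chosen after the data were seen. Unnamed predicted genes were passed over unless among the 3 largest. Some genes that this rule selects are not reported here.

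The tests were run on simulated counts with the means, library sizes and dispersions of these 9 libraries over 13042 genes, 200 of them changed. For the comparison of formoterol with vehicle, the edgeR test recovered 44% of the genes changed 2-fold and 77% of those changed 4-fold, with 2 false calls among 123. The list test, on counts with only 1 list lowered (by 0.5 on the log2 scale), recovered it and called 0 of the 39 others. Genes were drawn independently there, while the real respiratory chain list had an estimated correlation of 0.67. That run therefore says nothing about false list calls where genes vary together. Libraries of a group were also compared in pairs. The chi-square per degree of freedom was at least 24.7 in every pair, so no library was a copy of another.

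Alternatives were other normalizations, other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, protein-coding genes only, a test against a 1.2-fold change, removal of mitochondrially encoded genes, and leaving out each library in turn. Gene length came from the deposited table. GC content and transcript length came from a reference annotation of the earlier mouse build GRCm38, matched by gene identifier for 98.9% of the genes tested, with none of its coordinates used. Other files of the study, such as reads, were not analysed here.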

Results

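Bulk liver RNA was compared between 4 vehicle-treated and 5 formoterol-treated male C57BL/6J mice, all given the high-fat diet over 20 weeks. Formoterol is a long-acting beta-adrenergic agonist, a class of drug that signals through cyclic AMP. The comparison asks which liver transcripts differed after 4 weeks of daily formoterol at 1 mg/kg on that diet. Libraries held between 12336665 and 20339665 counts, and totals differed between the groups by less than the spread within them (exact permutation p = 0.81). Group membership follows the suffix of the column names.

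As groups, nuclear-encoded genes of the respiratory chain, genes of the urea cycle and amino acid catabolism, and hepatocyte marker genes rose in the formoterol livers. Cell cycle genes, collagen and fibrosis genes, lipid droplet genes and inflammatory cytokine genes fell. Median log2 fold changes were 0.50 for 76 respiratory chain genes, 0.42 for 31 urea cycle and amino acid genes, −0.59 for 24 cell cycle genes and −0.72 for 36 collagen and fibrosis genes (−1.19 without formoterol library M49). These calls are by camera at its preset correlation, which called 18 of 40 lists, 7 higher and 11 lower. With a correlation estimated from the data none of the 18 passed (smallest adjusted p = 0.194 with an estimated correlation), and by fry only the cell cycle list did (adjusted p = 0.0157), which ended without any 1 of M56, M58 or M59 (adjusted p from 0.0895 to 0.168). Fry called 8 lists without M49 and 2 without M60.

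No single gene passed the edgeR test with all 9 libraries (smallest Benjamini-Hochberg adjusted p = 0.136). At an unadjusted p under 0.05 there were 1899 genes, 1178 higher and 721 lower, where chance gives 652 on average. Chance counts can lie far from that average: 7 of 100 splits of the 9 libraries, the real one included, gave at least 1899. The count was 1203 without vehicle library M56 and 2981 without formoterol library M49. Other tools differed: DESeq2 called 316 genes (260 higher, 56 lower), limma-voom 0 and limma-voom with sample quality weights 1374. Those weights were 3.51 for formoterol library M47 and 0.369 to 0.665 for the other formoterol libraries. Without formoterol library M49, edgeR called 702 genes, 442 higher and 260 lower, and without vehicle library M60 it called 4 (Acmsd higher; Lars2 and 2 genes without a symbol lower), which were picked out after their values were seen.

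The genes with the smallest p were separated between the groups library by library in most cases, which their selection by p favours. With all 9 libraries none of the genes named in this paragraph passed the edgeR test, while DESeq2 called B3galt1, Acmsd, Ces3b, Mpv17l, Dsp and Nr1d1 (adjusted p from 2.33e-05 to 0.0013, and none given for the others) and limma-voom with sample quality weights called each of them. Pnldc1 (ENSMUSG00000073460; chromosome 17, 13107616 to 13129117 on mm39), an exonuclease that trims piRNAs, had 7.73 ± 1.04 CPM in the formoterol livers against 16.1 ± 1.96 in the vehicle livers (log2 fold change −1.06, SE 0.17, edgeR adjusted p = 0.136). Zfp969 (chromosome 2, 175484016 to 175495439), a zinc finger gene, had 6.33 ± 1.90 CPM against 1.31 ± 0.62. B3galt1 (chromosome 2, 67396215 to 67953033), a galactosyltransferase, had 24.5 ± 7.11 CPM against 10.3 ± 1.83, with formoterol library M46 at 37.2. Acmsd (chromosome 1, 127657150 to 127695715), an enzyme of tryptophan breakdown that limits NAD synthesis from tryptophan, had 17.6 ± 4.04 CPM against 7.17 ± 2.36, and passed without vehicle library M60 (edgeR adjusted p = 0.0334). Ces3b, a carboxylesterase, had 414 ± 152 CPM against 145 ± 34.4, with M49 inside the vehicle range at 181.1. Mpv17l had 37.1 ± 7.26 CPM against 19.6 ± 2.88. Lower values were found for Spon2, a secreted matrix protein (1.82 ± 0.48 CPM against 5.63 ± 0.91), Dsp, which encodes the desmosomal protein desmoplakin (9.45 ± 2.56 against 19.8 ± 3.24), Col5a2 and Nr1d1. Over all genes tested, 631 (4.84%) had groups that did not overlap, 320 higher and 311 lower. Chance gives 1.59% on average, and how far a chance share can lie from that average was not tested.

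**Figure D1:**
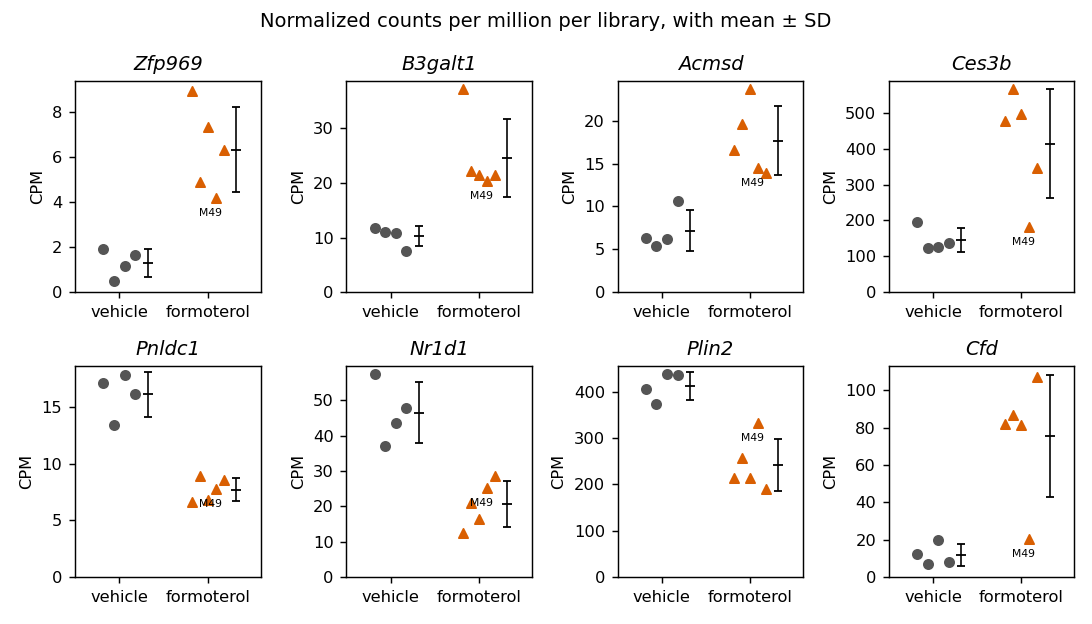
Normalized CPM (vertical axes from 0) of 8 genes in each library, for 4 vehicle (grey circles) and 5 formoterol livers (orange triangles), with the mean and SD at the right of each group. For Zfp969, B3galt1, Acmsd, Pnldc1, Nr1d1, Plin2 and Cfd no formoterol value lies within the vehicle range. For Ces3b library M49 does, and none of the 8 genes passed the edgeR test with all 9 libraries. Most were picked for a small p or a large change, which favours such separation.

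The respiratory chain list stood out by the number of its genes. Of its 76 genes, 70 had a positive log2 fold change, and 46 passed edgeR when adjusted over the list alone, all higher (camera adjusted p = 1.57e-21, and adjusted p = 0.489 with an estimated correlation). Over all genes tested edgeR called 0 of them, with 49 higher and 0 lower at an unadjusted p under 0.05, limma-voom 0, DESeq2 19 and limma-voom with quality weights 38, all higher. The count adjusted over the list alone was 0 without any 1 of M46, M48, M56, M58 or M59, and 15 without M47. At an unadjusted p under 0.05 the count higher was 31 without M56. It was 41 to 56 without any 1 of M46, M47, M48, M49, M58, M59 or M60. Atp5h and Atp5j, subunits of the ATP synthase, had 323 ± 69.0 CPM against 189 ± 42.8 and 265 ± 44.6 against 161 ± 36.8. Uqcr10 of complex III had log2 fold change 0.75 (SE 0.19) and Ndufa11 of complex I 0.69 (SE 0.18), with edgeR adjusted p of 0.159 and 0.171 and DESeq2 adjusted p of 0.0149 and 0.0231. The 13 mitochondrially encoded genes were not called (camera adjusted p = 0.987). Their share of counts was 28.9 ± 4.37% in vehicle and 24.1 ± 8.78% in formoterol libraries (exact permutation p = 0.357), and the values of mt-Atp6 and mt-Atp8, which overlap on the genome, are uncertain. The list of mitochondrial biogenesis, dynamics and mitophagy genes was not called either (camera adjusted p = 0.374), although Clpp, a matrix protease, had log2 fold change 0.74 (SE 0.18), Ucp2 −1.005 (SE 0.28) and Esrra 0.52 (SE 0.17). Ppargc1a, the coactivator that drives mitochondrial biogenesis, had 7.17 ± 1.40 CPM against 7.07 ± 1.90, a log2 fold change of 0.02 that turned negative under upper-quartile or library-total scaling and without any 1 of M46, M47, M48, M59 or M60 (−0.10 to −0.031). Short genes ranked higher in the formoterol libraries among the protein-coding genes tested (Spearman correlation of log2 fold change with gene length −0.245 across these 11743 genes, which are not independent replicates), and the median length was 1778.5 bp for the respiratory chain genes against 4229 bp for all 13042 genes tested, of any biotype.

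Genes of the urea cycle and amino acid catabolism rose with the respiratory chain (camera adjusted p = 1.6e-07, and adjusted p = 0.489 with an estimated correlation). Of 31 genes, 28 had a positive log2 fold change, and adjusted over the list alone 12 were higher and 1 was lower, a count that became 0 without any 1 of M47, M48, M56 or M59, and 3 higher and 1 lower without M58. Asl of the urea cycle had 528 ± 80.2 against 327 ± 86.5. The gene lower was Bckdha, a subunit of the branched-chain keto acid dehydrogenase, with 11.3 ± 4.03 CPM against 21.5 ± 2.81. Periportal hepatocyte markers, 9 of 15 of which sit in other lists, were also called higher (median 0.36, and 0.57 without vehicle library M60; camera adjusted p = 0.00934, and adjusted p = 0.489 with an estimated correlation), with Arg1 at 2183 ± 530 CPM against 1351 ± 259 and Pigr, the receptor that carries IgA into bile, at 912 ± 94.4 against 584 ± 26.7. Adjusted over the periportal list alone 5 genes were higher and 2 lower by edgeR, with 1 higher and 0 lower without M56 or M59. The periportal markers Cyp2f2 and Hsd17b13 had log2 fold changes of −0.67 and −0.89, so the call does not describe all markers of the list. Pericentral hepatocyte markers were not called (median 0.15, camera adjusted p = 0.424).

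Hepatocyte markers rose with a median of 0.35 over 19 genes (camera adjusted p = 3.00e-04, and adjusted p = 0.536 with an estimated correlation). Apoa1, the main protein of high-density lipoprotein, had 15870 ± 2779 CPM against 8933 ± 1276, Serpina1c 2405 ± 804 against 1264 ± 178 and Apoc3 3164 ± 747 against 2139 ± 446. Alb had 85080 ± 13030 CPM against 66920 ± 4634 (log2 fold change 0.35, SE 0.17, edgeR adjusted p = 0.373). The acute phase list was called higher with a median of 0.50 over 31 genes (camera adjusted p = 2.80e-04, and adjusted p = 0.684 with an estimated correlation), and the call ended without formoterol library M46 (median 0.13, adjusted p = 0.052). The median was 0.27 after a correction for gene length and GC content, and the list was still called. Its genes with the smallest p were Fetub, a fetuin secreted by hepatocytes (1099 ± 311 CPM against 529 ± 44.6), Orm1, Serpina3k and Saa4. The list pools genes without regard to the direction each takes in an acute phase response, so its call alone does not show one.

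Lipid droplet and triglyceride turnover genes fell with a median of −0.20 over 24 genes, −0.31 without M49 (camera adjusted p = 8.69e-04, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone 8 genes were lower and 0 higher by edgeR, with 1 lower without M59 and 5 without M58. Over all genes tested edgeR called 0 of them, with 8 lower and 1 higher at an unadjusted p under 0.05, limma-voom 0, DESeq2 5 and limma-voom with quality weights 9, all lower. Plin2, the main coat protein of hepatocyte lipid droplets, had 242 ± 55.9 CPM against 414 ± 30.3 (log2 fold change −0.77, SE 0.17, edgeR adjusted p = 0.159, DESeq2 adjusted p = 0.00243). Hsd17b13, a lipid droplet enzyme, had 118 ± 52.6 CPM against 219 ± 46.96, Cideb 30.5 ± 7.92 against 54.1 ± 13.5 and the monoglyceride lipase Mgll 183 ± 42.2 against 281 ± 38.4. Fatty acid synthesis genes were called lower (median −0.28 over 24 genes, camera adjusted p = 0.0401, and adjusted p = 0.742 with an estimated correlation), with 3 genes lower and 2 higher at an unadjusted p under 0.05, and 7 lower and 1 higher without M49. Other libraries left out in turn gave 0 to 5 lower and 0 to 3 higher. Elovl5 had 853 ± 274 CPM against 1374 ± 230 and Me1 153 ± 72.2 against 246 ± 51.5, while Nr1h3, which encodes the oxysterol receptor LXR alpha, had 55.5 ± 7.23 against 42.3 ± 5.24 and Mid1ip1, an activator of acetyl-CoA carboxylase, 57.6 ± 18.5 against 41.3 ± 7.08. Fasn had 486 ± 385 CPM against 655 ± 95.7, with a log2 fold change of −0.43 that was −0.99 without M49 and −0.17 without M46. The median was −0.52 without M49 and −0.11 without M46, and the call ended without any 1 of M46, M48, M50, M59 or M60 (adjusted p from 0.0554 to 0.7). Srebf1, the regulator of that pathway, had log2 fold change 0.10 (SE 0.18), negative under library-total scaling. Fatty acid oxidation and PPAR alpha targets were called lower (median −0.16 over 38 genes, camera adjusted p = 0.0401, and adjusted p = 0.684 with an estimated correlation), which ended without any 1 of M47, M49, M50, M58, M59 or M60 (adjusted p from 0.0564 to 0.329). Acadvl, which starts the oxidation of very long chains, had 19.9 ± 3.72 CPM against 34.2 ± 4.61, Cpt1a, which gates entry of fatty acids into mitochondria, 251 ± 36.7 against 332 ± 26.7, Pdk4 5.63 ± 2.51 against 11.6 ± 4.04 and Aldh3a2 and Pex11a log2 fold changes of −0.48 each.

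Cell cycle genes fell, and every formoterol library scored below every vehicle library (−0.30 ± 0.19 against 0.38 ± 0.09, exact permutation p = 0.00794, the smallest possible; 0.159 adjusted over the lists). The camera adjusted p was 8.69e-04, and adjusted p = 0.194 with an estimated correlation. Of 24 genes, 19 had a negative log2 fold change, and adjusted over the list alone 4 were lower and 1 was higher by edgeR. That count was 7 lower and 1 higher without M49 and 0 without any other 1 library. Over all genes tested edgeR and limma-voom called 0 of them, DESeq2 0 lower and 1 higher and limma-voom with quality weights 5 lower and 1 higher. DESeq2 gave an adjusted p to only 5429 genes and none to Mcm4, Mcm2 or Cdkn1a, so its count says nothing about these genes. Mcm4 and Mcm2, helicase subunits that license replication, had 1.47 ± 0.79 CPM against 3.59 ± 0.38 and 1.83 ± 0.63 against 3.82 ± 1.06. Cdkn1a, an inhibitor of the cell cycle that the list pools with its drivers, had 0.31 ± 0.43 CPM against 2.01 ± 0.47. The fall of the list is therefore not by itself a measure of cell division. Tk1, a thymidine kinase of S phase, went the other way with 21.9 ± 11.6 CPM against 7.88 ± 2.08. Most of these genes lie at a few CPM, which limits the precision of single values.

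Collagen and fibrosis genes fell by the largest median of the lists with more than 2 genes tested (camera adjusted p = 5.98e-08, and adjusted p = 0.566 with an estimated correlation), with 34 of 36 negative. Adjusted over the list alone 1 gene was lower by edgeR, and 17 were lower without M49. Col5a2, a fibrillar collagen chain, had 0.80 ± 0.21 CPM against 3.11 ± 0.64 (log2 fold change −1.94, SE 0.36, edgeR adjusted p = 0.151), Fbn1 0.64 ± 0.27 against 1.79 ± 0.17 and Mmp13 0.46 ± 0.40 against 1.29 ± 0.36. The median was −1.19 without M49. Scores were −0.44 ± 0.95 in the formoterol and 0.55 ± 0.40 in the vehicle libraries (exact permutation p = 0.0873), with M46 at −1.70 and M49 at 0.88. Col1a1 and Col3a1 had 9.82 ± 13.0 CPM against 26.8 ± 16.5 and 33.9 ± 19.6 against 57.4 ± 20.4. M49 had 32.3 CPM of Col1a1, and without it the log2 fold change of Col1a1 went from −1.43 (SE 0.97) to −2.66 (SE 0.77, edgeR adjusted p = 0.0965).

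Markers of several other liver cell types were called lower beside these genes. Stellate cell and fibroblast markers had a median of −0.28 (camera adjusted p = 0.0296, and adjusted p = 0.726 with an estimated correlation), a call that ended without any 1 of M46, M47, M56 or M59 (adjusted p from 0.0583 to 0.362), with a median of −0.10 without M46 and −0.46 without M49. Endothelial markers had a median of −0.28 (camera adjusted p = 0.0104, and adjusted p = 0.697 with an estimated correlation), with Wnt2, Cdh5, Fcgr2b and Stab1 among them, and the call ended without M46 (median −0.14, adjusted p = 0.28; −0.45 without M49, and −0.17 after the correction for length and GC content, still called). Monocyte and lipid-associated macrophage markers had a median of −0.47 (camera adjusted p = 0.0145, and adjusted p = 0.684 with an estimated correlation), which ended without M46 (adjusted p = 0.104) or M56 (adjusted p = 0.0929), and the median was −0.27 without M46 and −0.88 without M49. Lyz2 had 21.4 ± 7.53 CPM against 34.6 ± 10.3, Cd9 11.8 ± 4.08 against 18.5 ± 5.38, Ccr2 1.97 ± 1.69 against 4.72 ± 3.12 and Cd14 1.03 ± 0.48 against 1.97 ± 0.82. Kupffer cell markers were not called (median −0.03, camera adjusted p = 0.887), nor were those of cholangiocytes, T and NK cells, B and plasma cells, neutrophils, erythroid cells or adipocytes (camera adjusted p from 0.483 to 0.987). For T and NK cells and for neutrophils only 2 genes each were tested, too few to assess those cells. Between 7 and 10 were tested for cholangiocytes, B and plasma cells, erythroid cells and adipocytes. The list of exocrine pancreas, muscle, kidney and mesothelium markers was called higher on 2 genes, Cela1 (14.9 ± 5.37 CPM against 6.34 ± 1.19) and Mylpf (0.95 ± 0.29 against 0.81 ± 0.59), with adjusted p = 0.0398, and adjusted p = 0.489 with an estimated correlation; it ended without any 1 of M46, M47, M58 or M60 (adjusted p from 0.052 to 0.41), and its median of 0.71 became 0.077 without M58 and −0.070 without M60, where Wt1 was also tested. Nuclear and retained RNAs, a sign of RNA quality, were not called (camera adjusted p = 0.324).

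Inflammatory cytokine and chemokine genes fell with a median of −0.41 and 19 of 21 negative (camera adjusted p = 0.00934, and adjusted p = 0.489 with an estimated correlation), a call that ended without M46 (median −0.22, adjusted p = 0.0552), while the median was −0.87 without M49. Cxcl10 had 1.52 ± 0.29 CPM against 3.31 ± 0.75, Il1a 1.33 ± 0.79 against 2.94 ± 0.38 and Ccl5 0.27 ± 0.27 against 0.80 ± 0.23, while Il18 had 16.5 ± 4.84 against 9.09 ± 2.14. NRF2 antioxidant genes were called lower (median −0.24, camera adjusted p = 0.0379, and adjusted p = 0.489 with an estimated correlation), which ended without any 1 of M50, M59 or M60 (adjusted p from 0.0775 to 0.154), and the median was −0.16 without M49. Gstm1, a glutathione transferase, had 1117 ± 291 CPM against 1840 ± 111 and Ephx1 266 ± 37.0 against 372 ± 19.6, while Sod1 had 785 ± 132 against 518 ± 146. The unfolded protein and integrated stress response list was not called (camera adjusted p = 0.239). Gdf15, a stress-induced hormone in that list, had 2.37 ± 1.43 CPM against 7.54 ± 1.49, Calr 1122 ± 194 against 832 ± 24.5, Sdf2l1 15.9 ± 5.22 against 9.28 ± 2.96 and Syvn1 25.97 ± 4.35 against 36.4 ± 4.79.

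Genes of the adrenergic pathway that formoterol acts on were called lower as a list (median −0.25 over 29 genes, camera adjusted p = 0.0392, and adjusted p = 0.684 with an estimated correlation), which ended without any 1 of M46, M48, M56, M58 or M60 (adjusted p from 0.0554 to 0.144). The median was −0.46 without M49 and −0.16 without M46, and the correction for length and GC content also gave −0.16 and ended the call (adjusted p = 0.191). Adrb3 had 7.23 ± 2.67 CPM against 4.56 ± 1.97, and Adrb1 was too rare to test, with 75 counts over the 9 libraries. Pde4a and Pde4b, which degrade cyclic AMP, had log2 fold changes of −1.40 (SE 0.45) and −0.50 (SE 0.21), Gnas −0.94 (SE 0.42) and Grk6 −0.51 (SE 0.24). The list of CREB target genes was not called (camera adjusted p = 0.119), with Btg2 at 3.57 ± 1.67 CPM against 7.47 ± 2.02, Ier2 at 21.4 ± 6.20 against 14.0 ± 3.09 and Crem at 12.7 ± 0.90 against 10.1 ± 0.92. Gluconeogenesis (camera adjusted p = 0.641) and glycogen metabolism (0.0519) were not called. Pck1 and G6pc, the enzymes at both ends of glucose synthesis, had log2 fold changes of 0.09 (SE 0.21) and −0.15 (SE 0.43). The value for Pck1 was negative under library-total scaling and without M50 or M56 (−0.029 and −0.026). That for G6pc was −0.56 without M49 and positive without M46 or M59 (0.0032 and 0.017). Fbp1 had 151 ± 37.0 CPM against 232 ± 48.97, Eno1 198 ± 83.3 against 314 ± 26.1, Pgam1 42.0 ± 9.14 against 57.2 ± 12.2 and Gpt 173 ± 25.5 against 126 ± 30.1. In glycogen metabolism, Phkg2 had log2 fold change −0.78 (SE 0.23), Ppp1r3g −1.598 (SE 0.58), Gbe1 −0.30 (SE 0.15) and Ppp1r3b 0.36 (SE 0.19).

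Bile acid genes were not called as a list (camera adjusted p = 0.0599) but were called higher without M49 (adjusted p = 0.0152, and adjusted p = 0.363 with an estimated correlation). With all 9 libraries 10 of 27 genes were higher and 3 lower at an unadjusted p under 0.05, and 11 higher and 3 lower without M49. Without any 1 of M46, M47, M48, M56, M58, M59 or M60 the count was 4 to 7 higher and 1 to 3 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 95.6 ± 20.2 CPM against 66.6 ± 16.5 (log2 fold change 0.52, SE 0.20, edgeR adjusted p = 0.242), Cyp2c70 171 ± 49.3 against 95.1 ± 27.9 and Akr1d1 326 ± 106 against 190 ± 61.0. Abcc2, which exports conjugates into bile, had 279 ± 67.8 CPM against 427 ± 55.0, and Abcc4 0.46 ± 0.25 against 1.44 ± 0.57.

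Clock genes went both ways, and the list was not called for a direction (camera adjusted p = 0.257), though fry's test for change in either direction passed (adjusted p = 0.00129), as it did for 17 of the 40 lists. With 1 library left out that test called 1 list (without M56 or M59) to 27 (without M49), the clock list each time (adjusted p from 3.01e-04 to 0.0285). Nr1d1, a clock repressor (chromosome 11, 98658758 to 98666159), had 20.7 ± 6.51 CPM against 46.5 ± 8.63 (log2 fold change −1.16, SE 0.22, edgeR adjusted p = 0.151). Tsc22d3 had 73.9 ± 13.5 CPM against 51.3 ± 8.35 and Wee1 5.54 ± 0.84 against 8.72 ± 1.597.

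The list of sex-biased liver genes pools 12 male-biased and 8 female-biased genes, so its direction alone tells of neither a male nor a female pattern. It was called higher with a median of 0.48 over 20 genes (camera adjusted p = 0.0303, and adjusted p = 0.489 with an estimated correlation). The call ended without M50 (adjusted p = 0.0586) or M60 (median 0.29, adjusted p = 0.0554). Hsd3b5, a male-biased steroid enzyme, had 53.2 ± 30.1 CPM against 0.98 ± 1.02, with formoterol library M49 at 0.78, and the male-biased Nudt7 had 369 ± 89.2 against 224 ± 42.9. Cyp2b9, a female-biased cytochrome, had 41.4 ± 18.7 CPM against 103 ± 48.5, and Atp6v0d2, also female-biased, 9.00 ± 1.92 against 4.64 ± 2.02. The insulin and growth hormone list was not called (camera adjusted p = 0.887), with Igf1 at 958 ± 241 CPM against 548 ± 22.9, Igfbp2 at 247 ± 93.9 against 100.8 ± 42.2, Socs2 at 14.6 ± 8.02 against 5.45 ± 3.07 and Pik3r1 at 46.8 ± 18.3 against 73.9 ± 10.3. The 22 lists not called had camera adjusted p from 0.0519 to 0.987.

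**Figure D2:**
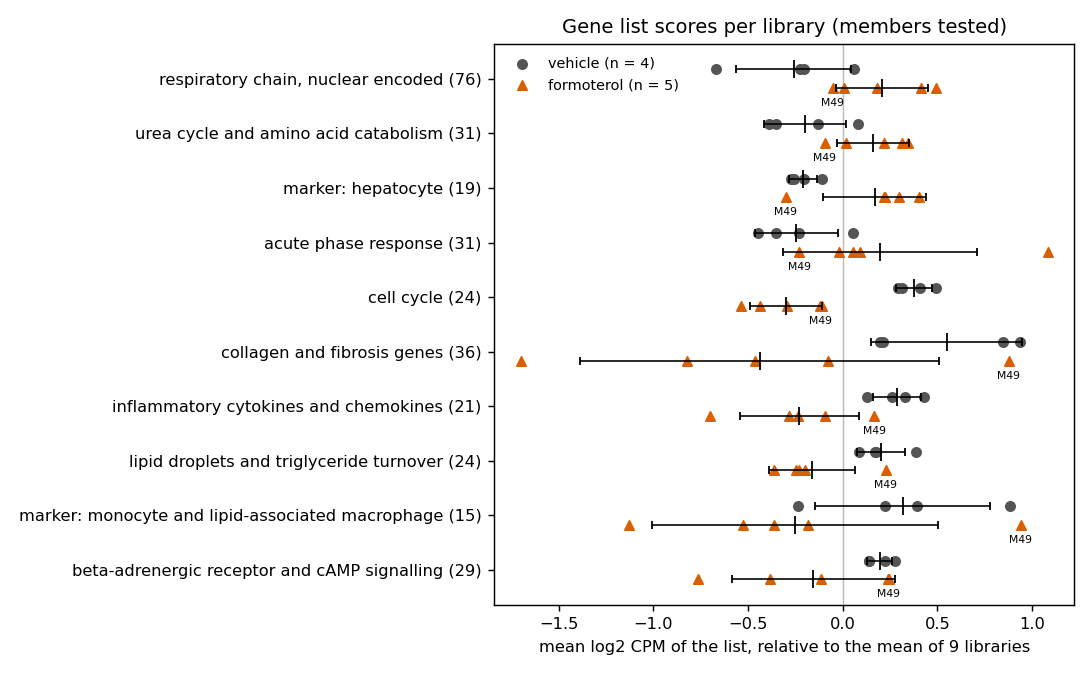
Scores of 10 gene lists per library, as the mean log2 CPM of the list's genes minus the mean of the 9 libraries (horizontal axis; genes tested in brackets), for 4 vehicle (grey circles) and 5 formoterol livers (orange triangles), with group means (vertical ticks) and SD. The cell cycle scores of the groups do not overlap. For every other list shown, including the respiratory chain, urea cycle and collagen lists, formoterol library M49 lies within or beyond the vehicle values.

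Formoterol library M49 lay far from the other formoterol libraries for lipid droplet genes and hepatocyte markers, and of the 9 libraries it was the one whose removal gave the most calls. The comparison without it is described here, a choice made after the data were seen. In that comparison 18 respiratory chain genes rose and 0 fell, 8 urea cycle and amino acid genes rose and 1 fell, 6 lipid droplet genes fell, 6 collagen and fibrosis genes fell, 4 monocyte and macrophage markers fell, and 4 cell cycle genes fell and 1 rose, each over all 12736 genes tested by edgeR. Cfd, the protease adipsin, rose by 2.92 on the log2 scale (SE 0.29, edgeR adjusted p = 6.37e-04), Hsd3b5 by 5.98 (SE 0.66) and Egfr, the epidermal growth factor receptor, by 2.11 (SE 0.33). The cytochrome Cyp2c54 rose by 2.72 (SE 0.23, edgeR adjusted p = 7.14e-05), and the major urinary protein genes Mup1, Mup7 and Mup12 rose by 3.61, 2.62 and 2.09, with Mup-ps20, a pseudogene of that family, at 3.10. Zfp969 and the chaperone gene Tsacc rose as well. Among the genes that fell most were the female-biased cytochromes Cyp2a4 (−4.21, SE 0.55) and Cyp2b13 (−4.01, SE 0.88), Cdkn1a (−4.001, SE 0.62), the receptor tyrosine kinase Ephb2 (−3.72), Mtmr11 (−3.79), Ly6d (−3.50), Ugt1a9 (−3.26), Gprc5b (−3.21), Rgs16, a regulator of G protein signalling (−2.42), and Cntnap1 (−2.42). Plin2, Igf1, Nr1d1, Apoa1 and Gdf15 passed in the same direction as with all 9 libraries. Camera called 18 lists, 8 higher and 10 lower, with bile acid genes gained and fatty acid oxidation lost against all 9 libraries, and 0 with an estimated correlation (smallest adjusted p = 0.259 with an estimated correlation). For Rgs16, Ly6d, Ephb2, Mtmr11 and Gprc5b, M49 had 95.2, 12.6, 4.92, 4.24 and 10.2 CPM, above every vehicle library.

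The groups did not separate on the first principal component of log2 CPM, which held 40.5% of the variance (exact permutation p = 0.119). M49 lay beyond the vehicle libraries on it and alone on the second component, which held 12.8%. Correlations between libraries were 0.963 to 0.977 within the vehicle group and 0.9 to 0.965 within the formoterol group. Fewer genes were detected in the formoterol libraries, 16830 ± 934 against 18310 ± 679 (exact permutation p = 0.0476). The most abundant transcript was mt-Co1, with 102600 ± 44220 CPM against 109400 ± 26460 (log2 fold change −0.09, SE 0.27; positive without M46 or M58, at 0.0082 and 0.066).

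**Figure D3:**
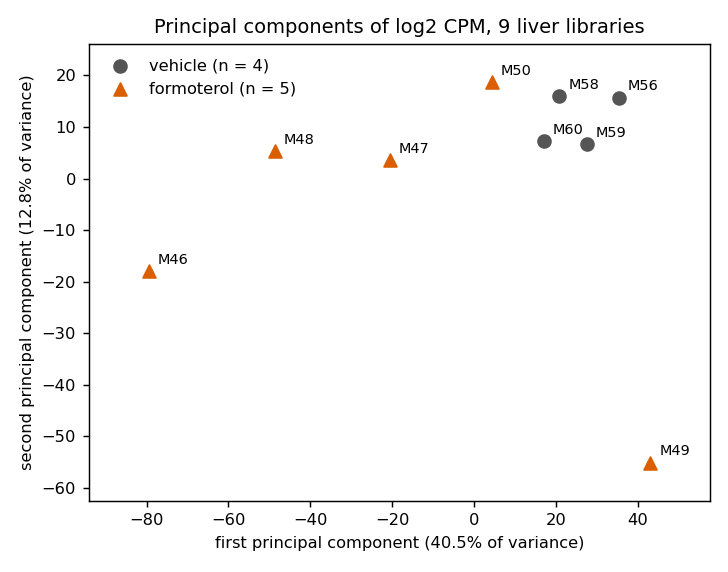
First (horizontal, 40.5% of variance) and second (vertical, 12.8%) principal components of log2 CPM over 13042 genes, 1 point per library, vehicle as grey circles (n = 4) and formoterol as orange triangles (n = 5). The 4 vehicle libraries lie together, 4 formoterol libraries spread to lower values of the first component, and M49 lies apart at the bottom right.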

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

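The tests of depth in library M49, of cell type markers and of the count of called genes over splits of all 9 libraries were chosen after the results were seen, as was the comparison without M49. Of 138 groups of 4 or 5 libraries examined for a single library far from the rest, 8 held one, where chance gives about 7.

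Library M49 was the far one for lipid droplet genes, with a list score of 0.228 where the other formoterol libraries lay between −0.365 and −0.202, and for hepatocyte markers, with −0.3 against 0.218 to 0.404. Formoterol library M46 was far from its group for the acute phase response (score 1.084), for B and plasma cell markers (−1.601) and for B3galt1 (37.18 CPM). Vehicle library M56 had a fatty acid oxidation score of −0.011 where the other vehicle libraries had 0.13 to 0.156. Vehicle library M60 had a periportal hepatocyte score of 0.19 where the others had −0.266 to −0.216. Formoterol library M50 had 180000 CPM of mt-Co1, with the other formoterol libraries at 69310 to 94600.

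The number of genes called by edgeR rose from 0 to 702 when M49 was left out. On the 200 genes with the smallest p in a comparison made without it, where 0 is the vehicle mean and 1 the mean of the other formoterol libraries, M49 had a median position of 0.129. Vehicle libraries held out in the same way took −0.0401 to 0.543 and the other formoterol libraries 0.574 to 1.3, so a wrong label remains a candidate explanation, as does a treated animal that responded little, which these data cannot separate from it. Against a plain vehicle liver, M49 also lay away from the vehicle libraries on the second principal component. Depth and a few abundant genes are argued against, since its 20 most abundant genes held 43.4% of counts and its total was 18291571 counts, both within the range of the other 8 libraries.

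With all 9 libraries chance cannot be excluded: 7 of 100 splits drawn gave at least the 1899 genes at an unadjusted p under 0.05 of the real one (highest other 3350). The count of 0 genes called decides nothing, since all 100 splits reach it. The split that put M49 with the vehicle libraries called 1126 genes. That count points to M49 lying nearer to the vehicle libraries than to the other formoterol libraries, as a wrong label would also give. Without M49, 1 of 35 splits, the real one, called as many as 702 genes (highest other 1). M49 was singled out because leaving it out gave the most calls of 9 libraries left out in turn (0 to 4 for the others), and a share of 1 in 35 multiplied by those 9 choices is 0.257, so these splits are too few for a share under 0.05.

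Respiratory chain genes are short and collagen genes long, and fold changes followed gene length, from a median of 0.16 in the shortest 2349 protein-coding genes to −0.11 in the longest 2349. Per library, the correlation of expression deviations with gene length did not separate the groups (−0.084 ± 0.18 in formoterol against 0.142 ± 0.14 in vehicle libraries, exact permutation p = 0.0873). Against 10000 random lists matched on length, GC content and expression, the respiratory chain median of 0.50 lay at percentile 100 (random median 0.25) and the collagen median of −0.72 at percentile 0 (random median −0.18). The random lists were drawn gene by gene and lack the correlation within the real lists (estimated at 0.67 and 0.60). These percentiles therefore overstate how far the medians stand out. Medians after a correction for length and GC content were 0.35 and −0.64. That argues against such bias as the whole cause of either median, but it may hold a part. Camera at its preset correlation still called both lists after the correction. With an estimated correlation neither list was called before the correction (adjusted p of 0.489 and 0.566). A response to formoterol stays open as the biological explanation, as does the share of cell types.

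Camera at its preset correlation called hepatocyte markers higher and markers of stellate cells, endothelial cells and macrophages lower. With an estimated correlation none of these passed (adjusted p of 0.536, 0.726, 0.697 and 0.684), and the calls for the last 3 ended without M46. A larger share of hepatocytes in the formoterol pieces is a candidate explanation, which predicts that all other cell types fall alike. Kupffer cell markers had a median of −0.03 against −0.47 for monocyte and lipid-associated macrophage markers, but the difference of these scores did not separate the groups (exact permutation p = 0.444). Marker scores of bulk RNA cannot tell a shift in cell shares from a change within cells. The scores also spread too widely among 5 formoterol libraries to decide whether the other cell types fell alike.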

How the results depend on the processing

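The comparisons without M46 and M49 together, with length and GC offsets, and by exact permutation of list means were chosen after the data were seen. The count of genes called by edgeR was 0 with all 9 libraries and stayed 0 under the other normalizations, the stricter filters, limma-voom, a non-robust fit, protein-coding genes, a 1.2-fold minimum, removal of mitochondrial genes, and length and GC offsets. It was 263 with no low-count filter (191 higher, 72 lower), 316 with DESeq2 (260, 56), 1374 with limma-voom and quality weights (792, 582), and 323 without M46 and M49 (189, 134). Among the formoterol libraries the quality weight was 3.51 for M47, 0.369 for M49 and 0.596 to 0.665 for M46, M48 and M50. The formoterol side of that setting thus leaned on M47. Leaving out 1 library gave 0 to 702. DESeq2, quality weights and the comparison without M49 shared 268 called genes, 219 higher and 49 lower. DESeq2 gave no adjusted p to 18612 genes with counts. Beyond the libraries left out, the cause of these differences was not tested. Scaling by library totals shifted the fold changes by a median of −0.154.

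Camera called 18 lists at its preset correlation, 0 with an estimated correlation, 1 by fry and 0 by exact permutation of list means. Leaving out 1 library gave 11 (without M46) to 18 by camera, 0 each time with an estimated correlation, and 0 (without M56, M58 or M59) to 8 (without M49) by fry. Of the 18 lists, 7 kept their call and direction in each: lipid droplets, respiratory chain, urea cycle, collagen, cell cycle, hepatocyte and periportal markers. With length and GC offsets 14 lists were called, and 4 were lost whose adjusted p had been 0.0303 to 0.0401 and became 0.076 to 0.191. Their medians changed little for sex-biased genes (0.48, quartiles −0.25 and 0.96, to 0.45, quartiles −0.20 and 0.75) and fatty acid synthesis (−0.28, quartiles −0.45 and 0.051, to −0.24, quartiles −0.40 and 0.093), and more for beta-adrenergic signalling (−0.25, quartiles −0.51 and 0.014, to −0.16, quartiles −0.37 and 0.21) and the 2 pancreas or muscle markers (0.71 to 0.56), so these lost calls do not show that length and GC content account for the lists. The exact p of the first component was 0.103 to 0.127 with other gene sets and prior counts.

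Of the genes named, 6 not called changed sign. Under library totals log2 fold changes were −0.041 for Srebf1, −0.095 for Pck1 and −0.14 for Ppargc1a. Ppargc1a also had −0.028 with upper-quartile factors, −0.0099 at a mean count of 50 and −0.0089 with length and GC offsets, where Mylpf had −0.069. Without M46 and M49 mt-Co1 had 0.13. Leaving out 1 library gave −0.029 to 0.26 for Pck1, −0.070 to 0.83 for Mylpf, −0.40 to 0.066 for mt-Co1, −0.56 to 0.017 for G6pc and −0.10 to 0.16 for Ppargc1a. The cause was not tested.

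No paired analysis was possible because the columns carry no replicate number of the labels, so the planned fits with a replicate block were not run for genes, lists or named genes. Depth limits genes near 0.6 CPM, where a library of this size holds about 10 counts.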

Other observations

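The tests of ribosomal protein genes, of sex-biased genes and of the clock score were chosen after the results were seen.

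Cytosolic ribosomal protein genes were in none of the 40 lists. Of 75, 73 had a positive log2 fold change, with a median of 0.58, but their mean did not separate the groups (exact permutation p = 0.0635). Like the respiratory chain genes they are short, with a median length of 1830 bp. Cholesterol synthesis genes were not called (median −0.04 over 25 genes, camera adjusted p = 0.596, higher by camera and by their mean of 0.01), nor were xenobiotic metabolism genes (camera adjusted p = 0.202), glycolysis genes (0.257) or the interferon response (0.257).

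Apoa4, an apolipoprotein of triglyceride-rich particles, Csad of taurine synthesis and the lipid droplet coat gene Plin4 were among the 268 genes called by DESeq2, by limma-voom with quality weights and by edgeR without M49, and were picked after their values were seen. With all 9 libraries their log2 fold changes were −1.62, −1.49 and −1.07 (edgeR adjusted p of 0.191, 0.159 and 0.22).

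One hypothesis is that the male pattern of liver expression, which growth hormone pulses maintain, was stronger in the formoterol livers. The score of 12 male-biased genes minus that of 8 female-biased genes was 0.89 in the formoterol and −1.11 in the vehicle libraries, a difference that did not pass (exact permutation p = 0.127). The male-biased genes alone had an exact permutation p of 0.0556. Mup1, Mup7, Mup12, Cyp2c54 and Igf1 rose without M49, but they are outside that score. They were set beside it after their values were seen, so they do not test the hypothesis. M49 itself scored with the vehicle livers (Hsd3b5 at 0.78 CPM), so the hypothesis stays open.

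A second hypothesis is that the formoterol livers were at another clock phase, either through treatment or through the hour of collection, which is not given in the sources used here. The score of Arntl, Clock and Cry1 minus that of Nr1d1, Nr1d2, Dbp, Per3, Tef and Ciart was higher in every formoterol library (0.0093 to 0.483) than in every vehicle library (−0.906 to −0.0691), with an exact permutation p of 0.00794, the smallest possible. Without Nr1d1, whose value prompted the test, the groups overlapped and p was 0.0238 (exact). Cry1 and Ciart stayed in the score, with edgeR p of 0.0164 and 0.0418 before adjustment. Since the score was chosen after such values were seen, neither exact p can decide whether the phase differed. Clock itself, Per3 and Tef did not go in the direction of the score (log2 fold changes of −0.41, 0.02 and 0.15), so a shift in phase, if any, may be only part of the pattern.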
